A study of Bos taurus with 42 samples.

How the data were processed

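Small RNA under 200 nt was sequenced on an Ion Proton from pooled bovine oocytes and embryos, from ear fibroblasts and from cells derived from blastocysts, per the labels. The labels give 4 pools of 20 embryos in one place and 3 pools in another. IVF embryos came from semen of a Holstein bull, and NT embryos from fibroblasts of a cross-bred bull. Both were cultured with cumulus cells. The authors trimmed reads with Trim Galore, used builds bosTau8 and UMD3.1, and transformed counts with DESeq2, per the submitters' processing notes. Versions are not given in the sources used here.

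The deposited values are on a log2 scale after size-factor normalisation and variance stabilisation by the authors. Their inverse was tested on the table: above the lowest value of 1.3675, 100% of 188126 values came out as whole multiples of 1 step per library (tolerance 0.01 reads), so reads and size factors were recovered. The step was set so that the smallest value above the lowest in each library stood for 2 reads. The absolute scale of the reads and size factors rests on this choice. Listed reads per library ranged from 25119 to 3081186 (median 608571, second lowest 216225), and deposited size factors from 0.079 to 13.421. These are reads of the listed sequences, not of whole libraries. Size factors recomputed from sequences present in all libraries were 0.852 to 1.151 times the deposited ones, after division by the median ratio. This does not check the absolute scale. Only 116 of 12345 sequences were found in all 42 libraries (65 tRNA-derived, 36 miRNA and 1 piRNA), so the scaling rests on few sequences. All 12345 were found in NT 2-cell replicate 4, and 423 to 8919 in the others. Sequences found only in other groups are therefore not listed and cannot be called. Excesses of lower calls in later stages and in fibroblasts are subject to this limit, and so are the class and cluster shares. No 2 libraries were copies of each other.

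Classes came from the annotations in the table. Sequences annotated only to miRNAs of other species formed a class of their own and are not named. Where several sequences share a name they were numbered. piRNA sequences are named by their cluster. miRNAs with a mismatch to the annotation were kept out of the gene lists. A sequence was tested where it lay at least 1 log2 unit above the lowest value in at least 3 libraries, which left 12039.

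Group comparisons used limma 3.58.1 in R 4.3.3: 1 linear model over all 12 groups without covariates, eBayes with an intensity trend (30 residual and a median of 49.5 prior degrees of freedom), and Benjamini-Hochberg adjustment within each comparison at 0.05, with no minimum fold change. Comparisons were NT against IVF at 5 stages, each step of development in IVF and in NT, the difference between these steps, and fibroblasts against oocytes. Changes are on the variance-stabilised log2 scale, which understates the change of low sequences. Lists and classes were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it. The 11 lists were the miR-371/302 list (1 sequence, not tested), miR-17-92 and paralogs, the let-7 family, fibroblast and mesenchymal miRNAs, the DLK1-DIO3 imprinted cluster, epithelial and trophectoderm miRNAs, the miR-34 and miR-449a-d family, X-linked clusters, and miRNAs of cumulus and granulosa cells, of blood and serum, and of muscle and neural tissue. Several members belong to 2 lists. Counts of miRNAs and of list members are counts of sequences, and several can be forms of the same miRNA. Class shares were sums of 2 to the power of the value less the lowest, compared by two-sided exact permutation tests within stages and by 100000 permutations within stages over all stages. List means and tRNA fragment shares were compared by exact permutation tests. Wilson intervals (95%) are given for shares of single libraries and cover counting error only.

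The limma and camera tests, the class share tests, the donor and oocyte sets, the lists and the naming rule were set before the data were examined. The exact permutation tests of list means and of 5′ tiRNA shares, the piRNA cluster shares and the Wilson intervals were chosen after the data were seen. Named were the called sequences with the largest changes (8 miRNAs, 3 tRNA-derived RNAs and 2 piRNAs in each direction for NT against IVF, and 4, 1 and 1 for other comparisons), up to 4 called members of each list, and a fixed set of miRNAs. The text gives some of these. Of the fixed set, miR-371, miR-302a, miR-302b, miR-127, miR-381, miR-200b, miR-143 and miR-1246 had no sequence of exactly that name.

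Alternatives set in advance were no filter, a stricter filter, median centring, quantile normalisation, removal of the offset of the transformation, a fit of only the groups compared, no trend, library weights, the replicate number as a block, adjustment within classes, other set sizes and leaving out each library. Added after seeing the data were leaving out 2 IVF morula libraries, log2 CPM of listed reads (prior 0.5 reads), voom on recovered reads, lists tested among miRNAs only, lists with mismatched forms, and shares of recovered reads.

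The methods were tested on simulated reads. With all 12 groups in 1 model, simulated 2-cell embryos gave 612 false calls among 11936 tested, against 4 with the 2-cell libraries alone, and 8-fold changes were found in 74.2% and 60.6% of cases. In simulated blastocysts the shares found at 8-fold were 25.8% with all groups and 100% with the blastocyst libraries alone, and in simulated blastocyst-derived cells 40.9% and 68.2%. In the same order, shares at 4-fold were 58.2% and 23.9% in 2-cell embryos, 4.48% and 76.1% in blastocysts and 14.9% and 26.9% in derived cells. A lost call or a count of 0 in either fit does not exclude changes of that size. Counts from the fit of only the groups compared are therefore given beside the counts of the planned model. The exact permutation test gave an unadjusted p under 0.05 in 2.25% of 400 null simulations and in 99.5% with a shift of 5 SD. These simulations compared 4 values with 4, as in 2-cell embryos. Groups of 3 and 4 libraries, as at the other stages, were not simulated. Figures were drawn with matplotlib 3.10.9, and tables handled with pandas 2.3.3 and NumPy 2.4.6 in Python 3.11.15.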

Results

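Small RNA under 200 nt was sequenced from pools of bovine oocytes, from ear fibroblasts, and from embryos made by in vitro fertilisation (IVF) or by somatic cell nuclear transfer (NT, cloning). The 42 libraries fell into 12 groups. There were 3 metaphase II oocyte libraries and 3 ear fibroblast libraries. Embryos were collected as 2-cell stages on day 2, as 8-cell stages on day 3, as morulae on day 6 and as blastocysts on day 8, and cells cultured from blastocysts (blastocyst-derived cells) closed the series. The IVF groups held 4 libraries of 2-cell embryos, 3 of 8-cell embryos, 4 of morulae, 3 of blastocysts and 4 of blastocyst-derived cells. The NT groups held 4, 4, 3, 4 and 3 libraries at the same stages. The deposited table lists 12345 small non-coding RNA (sncRNA) sequences. Of these, 9474 were assigned to piRNA clusters, 907 were derived from tRNAs and 619 were annotated to bovine miRNAs (379 without a mismatch). The reads behind the table ranged from 25119 in IVF morula replicate 3 to 3081186 in NT blastocyst-derived cell replicate 4, with a median of 608571. Reads are not independent molecules, so precision set by reads covers counting error only.

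The composition of the small RNA pool asks how the maternal supply gives way to embryonic RNA. Oocytes were dominated by piRNAs, at 89.8% ± 1.74 of the listed signal (SD, n = 3). IVF 2-cell embryos held 84.9% ± 8.12 (n = 4) and NT 2-cell embryos 88.7% ± 4.44 (n = 4). The piRNA share was 73.2% ± 6.21 in IVF 8-cell embryos (n = 3) and 83.9% ± 6.15 in NT 8-cell embryos (n = 4). It had dropped to 28.0% ± 5.87 in IVF blastocysts (n = 3) and 21.5% ± 7.76 in NT blastocysts (n = 4), outside the range of the oocyte libraries. In blastocyst-derived cells piRNAs were nearly gone, at 0.188% ± 0.075 in IVF (n = 4) and 0.0931% ± 0.0102 in NT (n = 3), and fibroblasts held 0.581% ± 0.31 (n = 3). Fragments of tRNAs took up the largest share of blastocysts, at 45.8% ± 12.3 in IVF and 44.3% ± 7.21 in NT, against 4.36% ± 1.72 in oocytes. The miRNA share was 2.51% in oocytes, 12.8% ± 4.48 in IVF blastocysts and 15.7% ± 3.96 in NT blastocysts, and it reached 64.1% ± 19.5 in IVF and 70.4% ± 7.12 in NT blastocyst-derived cells. IVF morulae did not form a group of like libraries. Replicate 1 held 64.1% miRNA reads (95% Wilson interval 64.0% to 64.2%) and 0.143% piRNA reads (0.135% to 0.152%), while replicates 2 and 4 held 4.61% and 4.19% miRNA signal. Replicate 3, the library with the fewest reads, held 65.5% tRNA-derived reads (64.9% to 66.0%) and 14.7% piRNA reads (14.3% to 15.2%).

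**Figure D1:**
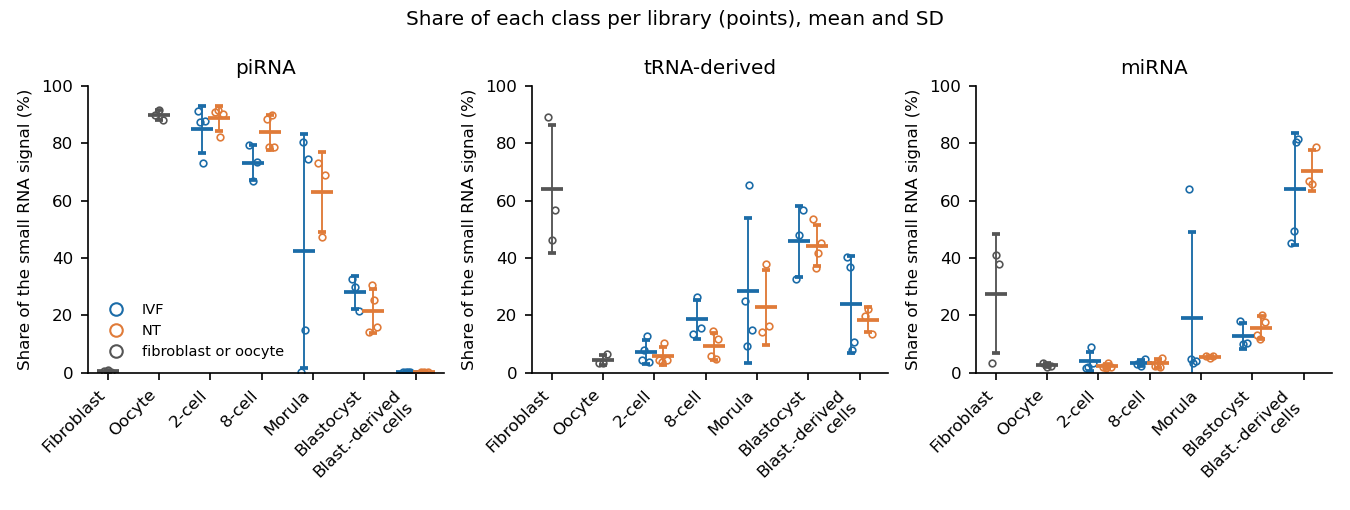
Share of the small RNA signal (%) taken by piRNAs, tRNA-derived RNAs and miRNAs in each group, with an open circle per library, a dash at the mean and a bar of 1 SD cut at 0 (blue IVF, orange NT, grey oocytes and fibroblasts). The piRNA share drops from 89.8% in oocytes to 28.0% in IVF and 21.5% in NT blastocysts.

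Whether cloned embryos hold a different mix than fertilised embryos was tested class by class. At the 8-cell stage the tRNA-derived share was 18.6% ± 6.88 in IVF and 9.15% ± 4.67 in NT embryos, a difference of -9.43 points (two-sided exact permutation test, p = 0.0857, adjusted p = 0.771 over 18 tests). The 8-cell piRNA share differed by 10.7 points in the other direction (exact permutation p = 0.171, adjusted p = 0.814). With stages as strata, NT minus IVF was 5.71 points for piRNAs (permutation p = 0.307), -4.72 points for tRNA-derived RNAs (permutation p = 0.254) and -1.24 points for miRNAs (permutation p = 0.826). None of these 18 tests passed the correction. At each stage after the 2-cell stage, 35 splits give no exact permutation p under 0.0286. A lone p of that size would not pass over 18 tests, so the tests within stages cannot exclude a difference. Without the IVF morula libraries labelled replicates 1 and 3, the pooled difference was -1.29 points for piRNAs, -1.40 for tRNA-derived RNAs and 1.68 for miRNAs.

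Within the tRNA-derived RNAs, 5′ tiRNAs (5′ tRNA fragments cut at the anticodon loop) held the largest part in blastocysts. Their tests were chosen after the data were seen. They made up 26.4% ± 20.8 of the tRNA-derived reads in oocytes (n = 3), 63.7% ± 3.75 in IVF 8-cell embryos (n = 3), 62.2% ± 8.17 in IVF blastocysts (n = 3) and 57.1% ± 1.25 in NT blastocysts (n = 4). NT blastocysts exceeded oocytes with no overlap between libraries (exact permutation p = 0.0286, the smallest that 35 splits can give, adjusted p = 0.171 over 9 tests). NT 8-cell embryos held 46.0% ± 14.8, which was 17.7 points lower than IVF (exact permutation p = 0.114, adjusted p = 0.206). In blastocyst-derived cells the 5′ tiRNA share was 66.6% ± 2.38 in NT and 36.6% ± 18.9 in IVF (exact permutation p = 0.0571, adjusted p = 0.171), with every NT library above every IVF library. Fibroblasts held 4.79% ± 1.35 and shorter 5′ fragments at 64.4% ± 37.3, with a range from 21.4% to 88.5% between the 3 libraries. Leader fragments of tRNA precursors fell from 3.79% ± 1.44 of the tRNA-derived reads in oocytes to 0.112% ± 0.0498 in IVF and 0.0865% ± 0.0388 in NT blastocysts.

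**Figure D2:**
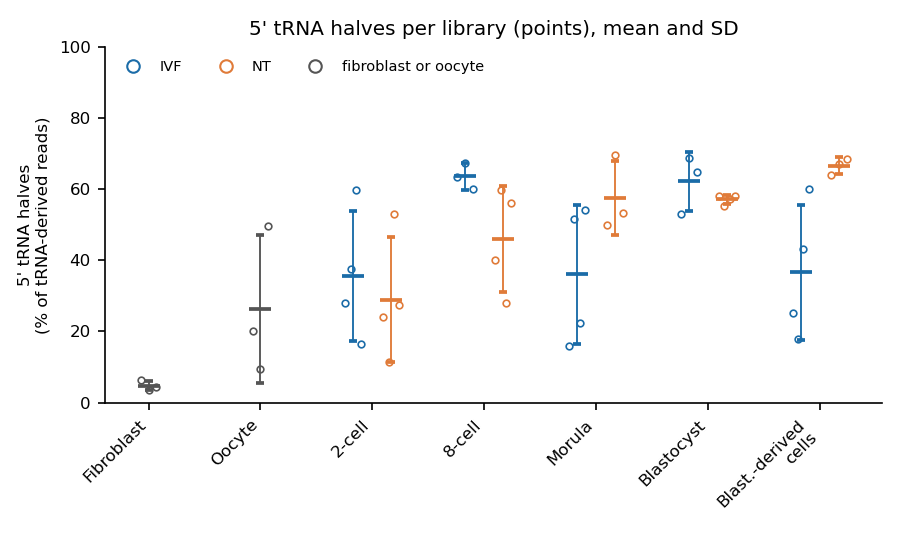
Share of the tRNA-derived reads (%) in 5′ tiRNAs by group, with an open circle per library, a dash at the mean and a bar of 1 SD. NT blastocyst-derived cells lie at 66.6% and IVF blastocyst-derived cells at 36.6% with a wide spread.

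The piRNA reads came from 616 named clusters, and a few supplied most of them. The cluster on chromosome 6 from 110178897 to 110333441 (coordinates of build UMD3.1/bosTau8, as the table names it) gave 32.8% ± 0.487 of piRNA reads in oocytes, 33.1% ± 0.789 in IVF 8-cell embryos, 33.8% ± 1.17 in IVF blastocysts and 34.0% ± 1.31 in NT blastocysts. The cluster on chromosome 17 from 62734087 to 62862016 gave 17.8% ± 0.84 in oocytes and 17.1% ± 0.486 in NT blastocysts. In IVF morulae the chromosome 6 cluster averaged 22.4% ± 15.7. In the other embryo groups its share stayed near the oocyte value while the piRNA share fell. In fibroblasts the same chromosome 6 cluster gave 0.219% ± 0.309 of the few piRNA reads, and a cluster on chromosome 3 from 80674203 to 80680024 gave 49.5% on average with a wide spread between the 3 libraries.

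The comparison of NT with IVF embryos at each stage asks where cloning changes the sncRNA profile. In 2-cell embryos, limma on all 12 groups called 275 of 12039 sncRNAs at an adjusted p under 0.05, 260 higher and 15 lower in NT. Of these, 244 were piRNAs, 17 tRNA-derived RNAs and 4 miRNAs. A fit of only the 2-cell libraries, which tests 8240 sncRNAs with its own estimate of the spread, called 0, with 269 at an unadjusted p under 0.05. Voom on recovered reads called 0, CPM of listed reads called 0, and libraries centred on their medians called 0. The median change of all sncRNAs was 0.34 on the log2 scale. NT 2-cell replicate 4 held all 12345 sequences, against 5513 to 6606 in the other NT 2-cell libraries. This median can come from that library alone, so it does not show a general shift. Quantile normalisation, which sets all libraries to 1 distribution, called 23 higher and 15 lower. The count was 877 without NT 2-cell replicate 3, 492 without replicate 1 and 429 without replicate 2. miR-18b-5p was higher in NT by 2.10 ± 0.61 (log2 change ± SE, adjusted p = 0.0455 by limma), with a mean of 10.0 normalised reads in NT and 0 in IVF. miR-216b was lower by -2.24 ± 0.61 (adjusted p = 0.0282), from 13.7 normalised reads in IVF to 0.898 in NT. A piRNA of the cluster on chromosome 23 from 13905000 to 14137856 was higher by 3.49 ± 0.61 (adjusted p = 0.000223). None of these 3 passed in the fit of only the 2-cell libraries.

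In 8-cell embryos, NT and IVF differed in 1 called sncRNA by limma, with 972 at an unadjusted p under 0.05. This piRNA of a cluster on chromosome 16 from 49219466 to 49228666 was higher in NT by 1.84 ± 0.37 (adjusted p = 0.0403). The fit of only the 8-cell libraries called 3 higher and 6 lower. Among them were 5′ tiRNAs of tRNA ValCAC, lower in NT by -2.72 ± 0.59 (adjusted p = 0.0107 by limma), of tRNA CysGCA (-2.94, adjusted p = 0.00794) and of tRNA MetCAT (-2.65, adjusted p = 0.0161). These were chosen after their values were seen. Voom, CPM and median centring each called 0 here.

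In morulae, limma called 0 sncRNAs between NT and IVF, with 1223 at an unadjusted p under 0.05. The fit of only the morula libraries also called 0 (124 at an unadjusted p under 0.05). Voom called 18 and CPM 11, all higher in NT. Leaving out the IVF morula libraries labelled replicates 1 and 3 called 4, all lower in NT. Without IVF morula replicate 4 the count was 664 and without replicate 2 it was 599, so the IVF morula group itself decided the result. In blastocysts, library weights called 19 sncRNAs higher and 317 lower in NT, quantile normalisation 5 and 13, and the fit of only the blastocyst libraries 0 and 2. limma with equal weights called 1 tRNA-derived RNA (74 at an unadjusted p under 0.05) of type tRF-1, a fragment from the 3′ end of a tRNA precursor. It averaged 61.1 ± 51.8 normalised reads in IVF (n = 3, range 23.4 to 120) and was at 0 in all 4 NT libraries, which is at least 35.2-fold lower against a floor of 3 reads per library, or at least 18.2-fold without IVF blastocyst replicate 4 (log2 change -4.39 ± 0.78, adjusted p = 0.00355 by limma). The call was lost without IVF blastocyst replicate 4, with libraries centred on their medians and without the intensity trend, and kept in the fit of only the blastocyst libraries (adjusted p = 3.5e-05). In blastocyst-derived cells limma called 0 (33 at an unadjusted p under 0.05), the fit of only those libraries 0 (47), voom 0 and CPM 1 higher and 7 lower.

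Families fixed before the data were examined showed where miRNAs differed as groups in blastocyst-derived cells. The DLK1-DIO3 imprinted cluster list, with 16 tested miRNA sequences, was lower in NT than in IVF cells by a mean of -0.92 (camera, adjusted p = 2.38e-69 with a preset correlation and 4.18e-09 with an estimated one). With adjusted p-values over all sncRNAs 0 members passed, and adjusted over the list alone 2 were lower. In a fit of only these cells, where 8 members were tested, the adjusted p was 1.74e-08 with the preset correlation but 0.54 with the estimated one. Against miRNAs only, the list kept an adjusted p of 0.0123 with the estimated correlation. Its mean was 1.49 ± 0.07 in NT (n = 3, range 1.44 to 1.57) and 2.40 ± 0.55 in IVF (n = 4, range 1.61 to 2.79) on the variance-stabilised log2 scale, with every NT library below every IVF library. An exact permutation test of these means, chosen after the data were seen, gave p = 0.0571 (adjusted p = 0.794 over 50 tests, smallest possible p 0.0286). A lone p of 0.0286 would not pass over 50 tests. The test therefore shows no difference between the libraries by itself and cannot exclude one. In CPM of miRNA reads, the cluster gave 2.47 to 12.4 in NT cells and 10.1 to 800.0 in IVF cells, so the libraries overlap on that scale. With quantile normalisation they overlap too, with a highest NT mean of 2.63 and a lowest IVF mean of 2.47. In blastocysts the list ran the other way, at 3.46 ± 0.27 in NT and 3.04 ± 0.10 in IVF (camera adjusted p = 0.000111, 0.33 with the estimated correlation, and exact permutation p = 0.0857). The change from blastocyst to derived cells differed between NT and IVF by -1.34 (camera adjusted p = 4.78e-29, 2.4e-05 with the estimated correlation).

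**Figure D3:**
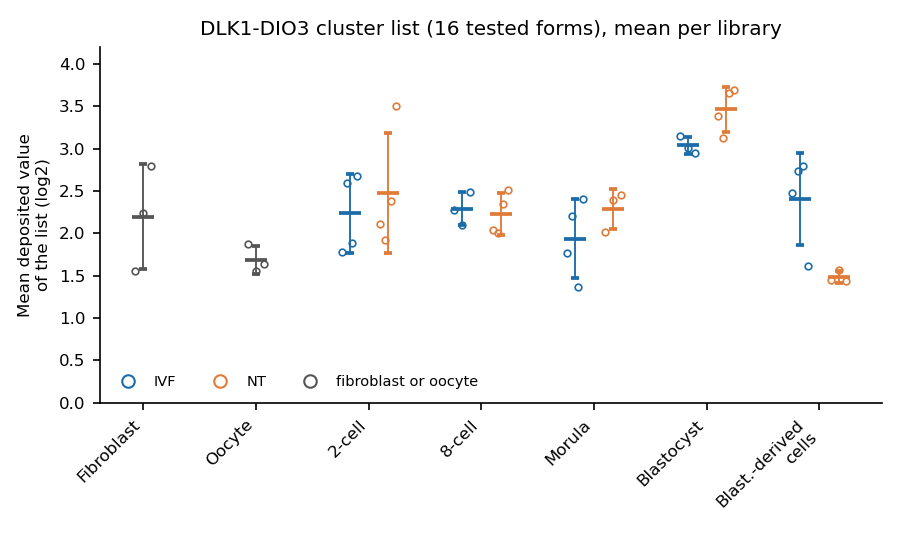
Mean variance-stabilised log2 value of the 16 tested DLK1-DIO3 miRNA sequences in each library (open circles), by group, with a dash at the mean and a bar of 1 SD (blue IVF, orange NT, grey oocytes and fibroblasts). On this scale NT blastocyst-derived cells lie between 1.44 and 1.57, below all IVF blastocyst-derived cells, which reach 2.79.

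Other lists in NT against IVF blastocyst-derived cells passed with the preset correlation, and 3 of them turned on IVF blastocyst-derived cell replicate 2. This library correlated more with fibroblasts (mean r = 0.905) than with its own group (0.892) and had the lowest 5′ tiRNA share of the derived cells, at 17.9%. The epithelial and trophectoderm list was higher in NT by a mean of 0.76 (camera adjusted p = 7.23e-23, estimated 0.0016), but lower without that library (adjusted p = 0.000676). The miR-34 and miR-449a-d family was higher by 0.71 (adjusted p = 9.12e-15, estimated 0.00178) and lower without that library (adjusted p = 0.569), and the miR-17-92 list was higher by 0.49 (adjusted p = 1.59e-12, estimated 0.0412) and lower without that library (adjusted p = 0.53). The fibroblast, X-linked, cumulus, blood and muscle lists were lower at adjusted p = 0.00235, 0.0203, 0.000226, 0.0252 and 0.026 and lost the call with the estimated correlation (0.427, 0.427, 0.111, 0.342 and 0.342). No member of these 8 lists passed over all sncRNAs or adjusted over the list alone. Fragments of serine tRNAs were lower in NT cells by a mean of -0.68 over 18 sequences (adjusted p = 4.62e-29, estimated 2.86e-07) and those of leucine tRNAs by -0.61 over 12 (adjusted p = 5.26e-17, estimated 1.27e-06). Serine fragments took 33.2% of tRNA-derived reads in fibroblasts, 1.07% to 12.9% in IVF and 0.485% to 3.9% in NT derived cells, so the libraries overlap. In the fit of only these cells serine kept an adjusted p of 0.0269 and leucine had 0.092. Glutamate, phenylalanine, threonine and tyrosine fragments were also lower and histidine fragments higher with both correlations. In 2-cell embryos the let-7 (adjusted p = 0.00827), epithelial (0.00845) and X-linked (0.0135) lists were lower in NT, and in blastocysts the let-7 (0.00983), fibroblast (0.00883) and blood (0.00655) lists. None held with the estimated correlation (0.667 for each of the 3 in 2-cell embryos, and 0.741, 0.741 and 0.442). No list passed in 8-cell embryos or morulae.

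The first cleavages test what changes between the oocyte and the early embryo, before most embryonic transcription. From oocyte to IVF 2-cell embryo, limma called 95 sncRNAs higher and 270 lower, and the fit of only these groups 10 higher and 1 lower, with 6 shared. Voom called 0 and CPM 1. The 5′ tiRNA of tRNA ValTAC went from 0 in the 3 oocyte libraries to 78.4 normalised reads, a change of 4.77 ± 1.00 (adjusted p = 0.0027 by limma, 0.00866 in the fit of only these groups). It also rose in NT 2-cell embryos, by 4.61 ± 1.00 (adjusted p = 0.00481). miR-451-5p rose by 3.55 ± 0.89 in IVF (adjusted p = 0.0127), and miR-1298-5p fell by 2.67 on the log2 scale (SE 0.52, adjusted p = 0.00108), but both lost the call in the fit of only these groups. From oocyte to NT 2-cell embryo limma called 223 higher and 70 lower, against 20 and 11 in the fit of only these groups, with 8 shared. The count was 513, 697 and 462 without NT 2-cell replicates 1, 3 and 4. Voom and CPM each called 0. miR-24-2-3p rose by 3.68 ± 0.82 (adjusted p = 0.0057) and miR-497 fell by 3.07 (SE 0.77, adjusted p = 0.0146), which lost the call in the fit of only these groups. Both steps share the oocyte libraries, so no overlap between them is given. No list passed in either step.

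Between the 2-cell and 8-cell stages, the number of called sncRNAs was low with all libraries but unsteady. In IVF embryos limma called 6 higher and 8 lower, and the fit of only these groups 9 higher and 1 lower, with 3 shared. miR-449a rose by 4.51 ± 0.99 (adjusted p = 0.0431, and 0.00376 in that fit), from 4.39 to 143 normalised reads. The 5′ tiRNA of tRNA ValCAC rose by 4.74 ± 0.90 (adjusted p = 0.0138, and 2.71e-05 in that fit), from 18.2 to 268 normalised reads. In NT embryos 4 were higher and 56 lower, against 2 and 2 in the fit of only these groups. The count in NT was 232 without NT 2-cell replicate 3, 123 without replicate 1 and 173 without replicate 4, and median centring called 0 higher and 200 lower. In IVF it was 196 without IVF 2-cell replicate 3, and 32 or fewer without any other library. The fibroblast and X-linked lists rose in NT (both adjusted p = 0.0169, estimated 0.754). The NT step differed from the IVF step in 7 called sncRNAs, all piRNAs lower in the NT step, and in 0 in the fit of only these groups. The largest was a piRNA of the cluster on chromosome 10 from 60315007 to 60321439, at -5.97 ± 0.93 (adjusted p = 0.000115 by limma), and it too lost the call in that fit.

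Genome activation falls between the 8-cell stage and the morula. In IVF embryos limma called 25 sncRNAs higher and 1510 lower, against 0 higher and 411 lower in the fit of only these groups (248 shared). The IVF count was 0 without IVF 8-cell replicate 2, 107 without 8-cell replicate 3, 27 and 38 without IVF morula replicates 1 and 3, and 2334 and 2649 without morula replicates 2 and 4. The median of all sncRNAs dropped by 0.67 on the log2 scale, and with each library centred on its median 4 were called higher and 0 lower. In NT embryos 32 were higher and 733 lower, with a median of -0.69, against 75 and 1270 in the fit of only these groups (671 shared). The NT count was 215 and 153 without NT 8-cell replicates 1 and 3, 1470 and 1301 without 8-cell replicates 2 and 4, and 153, 245 and 279 without NT morula replicates 2, 3 and 4. With centring 196 were called higher and 2 lower in NT. miR-378 rose in both, by 5.37 ± 1.01 in IVF (adjusted p = 0.00373, 37.1 to 1870 normalised reads) and by 5.50 ± 1.01 in NT (adjusted p = 0.00067, 24.1 to 1160). In the fit of only these groups it kept the call in NT and lost it in IVF. The miR-302a-3p/miR-302d-3p sequence was at 0 in all IVF and NT 8-cell libraries and at 70.8 to 149 normalised reads in the 3 NT morula libraries (5.42 ± 0.92, adjusted p = 0.000331). It was found in IVF morula replicates 2 and 4, at 50.1 and 63.4 normalised reads, and also in fibroblast replicates 3 and 4, at 8.68 and 66.6, and NT 2-cell replicates 2 and 4, at 13.4 and 3.59. Ribosomal and small nucleolar RNA fragments rose as classes in NT (both estimated adjusted p = 0.0198). The cumulus and granulosa list, which holds miR-378, rose in IVF with a mean of 0.86 (camera adjusted p = 2.03e-09, estimated 0.026, 4 members higher over all sncRNAs and 5 higher and 2 lower adjusted over the list alone). Its mean ranged from 3.46 to 5.61 between IVF morula libraries, and the rise was 0.46 without replicate 1 and 0.72 without replicates 1 and 3. Its adjusted p at the preset correlation over 14 alternatives, among them the fit without replicates 1 and 3, ran from 1.12e-14 to 0.00148. In NT its mean was 0.60 and its median -0.39 (adjusted p = 1.26e-05, estimated 0.18). Other lists that passed in this step lost the call with the estimated correlation, at 0.355 to 0.422 in IVF and 0.268 to 0.37 in NT, and several had a negative mean, since camera compares a list with all other sncRNAs. Without the IVF morula libraries labelled replicates 1 and 3, 8 were called higher and 3 lower in IVF.

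From morula to blastocyst the DLK1-DIO3 miRNAs, already found at low levels in earlier embryos, rose. The list rose in NT by a mean of 1.18 (camera adjusted p = 1.17e-15, estimated 0.00209), with 5 members higher over all sncRNAs and 6 adjusted over the list alone. It rose in IVF by 1.10 (adjusted p = 4.75e-15, estimated 0.00265), with 0 members over all sncRNAs and 6 adjusted over the list alone. In NT, miR-376c-3p rose by 4.78 ± 0.84 (adjusted p = 0.00199 by limma, 3.07 to 127 normalised reads) and miR-376e by 3.54 ± 0.64 (adjusted p = 0.00199). Over all sncRNAs, NT embryos had 7 higher and 159 lower (97 and 2539 in the fit of only these groups, 166 shared), with a median of -0.39. With median centring 3 were called higher and 0 lower, and without NT morula replicate 2 the count was 0, so the excess of lower sncRNAs depends on the scaling and on single libraries. IVF embryos had 1 called (474 at an unadjusted p under 0.05), the 5′ tiRNA of tRNA GlnTTG, higher by 3.61 ± 0.71 (adjusted p = 0.0305). The fit of only these groups called 0 (30 at an unadjusted p under 0.05). Without the 2 IVF morula libraries the IVF count was 30 higher and 1657 lower. Other lists (adjusted p = 0.000227 to 0.0157 in IVF and 0.00732 to 0.0495 in NT) lost the call with the estimated correlation. Ribosomal, small nuclear and small nucleolar RNA classes rose in IVF (estimated adjusted p = 0.045, 0.045 and 0.0266).

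Culture of blastocyst cells brought the largest change in miRNAs. The miRNA class rose against other sncRNAs in IVF (camera adjusted p = 5.82e-41, estimated 0.0263) and in NT (2.99e-59, estimated 0.00432). The let-7 family rose by a mean of 3.95 in IVF (adjusted p = 1.91e-53, estimated 2.22e-05) and 4.33 in NT (7.31e-77, estimated 8.07e-07). Of its 19 sequences, several of them forms of the same miRNA, 15 in IVF and 16 in NT were higher over all sncRNAs. Adjusted over the list alone, 19 of 19 were higher in each. The fibroblast and mesenchymal list rose by 3.69 in IVF (1.18e-87, estimated 2.39e-05, 32 of 48 members, 39 adjusted over the list alone) and by 3.96 in NT (8.88e-122, estimated 1.37e-06, 30 and 37 of 48). let-7c rose by 5.73 ± 0.96 in IVF (adjusted p = 2.55e-05 by limma) and by 6.72 ± 0.96 in NT (adjusted p = 1.37e-06). The miR-199a-2-5p/miR-199a-1-5p sequence rose by 7.84 ± 0.98 in IVF (adjusted p = 6.5e-08, 1.17 to 1080 normalised reads) and miR-199a-3p by 8.10 ± 1.04 in NT (adjusted p = 1.35e-07). miR-302a-3p/miR-302d-3p fell by 4.56 (SE 0.92, adjusted p = 0.00046) in IVF and by 5.30 (SE 0.92, adjusted p = 4.11e-05) in NT. The DLK1-DIO3 list fell in NT by a mean of 1.98 (camera Down, adjusted p = 6.29e-18, estimated 0.000369, 7 members lower over all sncRNAs, 9 adjusted over the list alone), and miR-376e fell by 4.43 (SE 0.64, adjusted p = 1.44e-06). The epithelial (2.69e-12, estimated 0.0125), miR-34 and miR-449a-d (1.7e-14, estimated 0.00162), X-linked (2.96e-19, estimated 0.00378) and cumulus (8.84e-07, estimated 0.0224) lists rose in NT, and the miR-17-92 list rose at 1.12e-08 (estimated 0.0631). In IVF the X-linked (1.82e-13, estimated 0.0256), cumulus (2.82e-07, estimated 0.0256) and miR-34 and miR-449a-d (2.15e-06, estimated 0.0465) lists rose, and the miR-17-92 and epithelial lists (both 0.00269) did not hold (estimated 0.402 and 0.355). Over all sncRNAs, IVF cells had 112 higher and 510 lower and NT cells 119 and 226, against 203 and 1240 and 314 and 1303 in fits of only these groups, with 606 and 345 shared. Sequences found only in derived cells are not listed, which limits the counts of higher sncRNAs. The IVF count was 389 and 330 without IVF blastocyst replicates 2 and 3, and the NT count 190, 204 and 181 without NT blastocyst-derived cell replicates 1, 3 and 4.

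**Figure D4:**
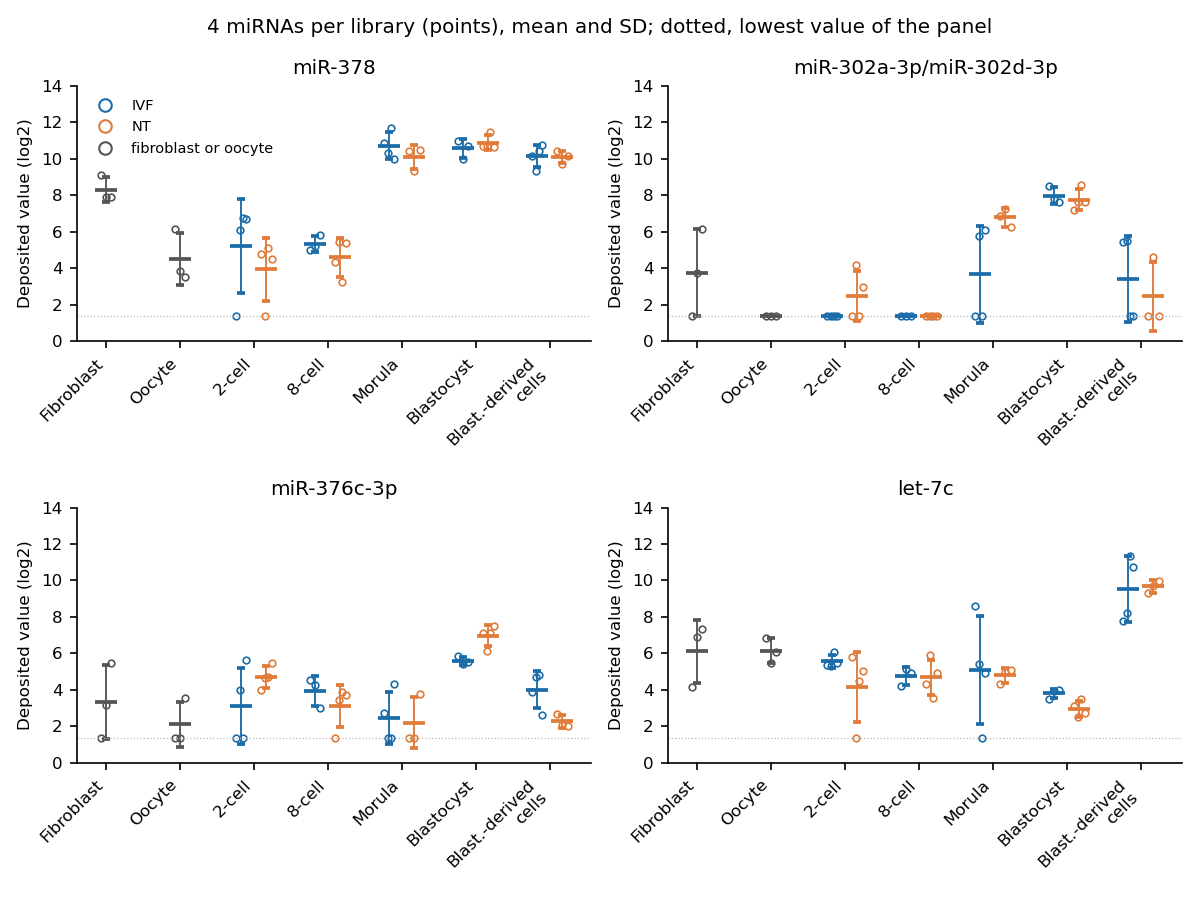
Variance-stabilised log2 values of named miRNAs by group, with an open circle per library, a dash at the mean and a bar of 1 SD (blue IVF, orange NT, grey oocytes and fibroblasts). miR-302a-3p/miR-302d-3p stays at the lowest value through the 8-cell stage in IVF and lies between 7.19 and 8.59 in NT blastocysts.

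Fibroblasts and oocytes bring together the donor and the recipient cell of the cloned embryo. limma called 164 sncRNAs higher and 4865 lower in fibroblasts than in oocytes, and the fit of only these groups 143 and 3421, with 3530 shared. All listed sequences were found in NT 2-cell replicate 4, so sequences found only in fibroblasts could not be called higher. The median change was -0.97, and median centring called 471 higher and 1900 lower. miR-184 was higher by 6.17 ± 0.96 (adjusted p = 1.3e-07) and miR-145 by 5.14 ± 1.09 (adjusted p = 5.65e-05). miR-205-5p was lower by -7.96 ± 1.08 (adjusted p = 4.67e-09) and miR-138-2-5p by -7.49 ± 1.02 (adjusted p = 5.43e-09). A 5′ fragment of serine tRNAs (SerTGA/SerAGA) was higher by 10.08 ± 1.17 (adjusted p = 1.17e-10), at a mean of 43700 normalised reads in fibroblasts. The fibroblast list had 20 members higher and 4 lower over all sncRNAs and 21 and 5 adjusted over the list alone (camera adjusted p = 1.72e-16, estimated 0.0875). The let-7, DLK1-DIO3, X-linked, cumulus, miR-17-92 and muscle lists also passed with the preset correlation only (estimated 0.0875 to 0.615). Of these, the miR-17-92, X-linked and muscle lists passed as higher against a falling background with mean changes of -0.98, -0.23 and -0.48.

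The miRNAs most enriched in fibroblasts or in oocytes ask whether cloned embryos lean to the donor cell. In 2-cell embryos both sets passed (camera adjusted p = 0.0148 for the 50 donor-high and 0.00972 for the 50 oocyte-high miRNAs) with mean changes of 0.06 and -0.02. They were flat against a median of 0.34 over all sncRNAs, which NT 2-cell replicate 4 alone can give. Among miRNAs only, both had 0.514 there. In morulae the donor-high miRNAs were lower in NT by a mean of -0.20 and the oocyte-high miRNAs higher by 1.22 (both 1.07e-05). Without the IVF morula libraries labelled replicates 1 and 3 both sets changed direction (7.61e-05 and 0.148). In blastocysts the oocyte-high miRNAs were lower by -0.52 (5.53e-06) and the donor-high miRNAs did not pass (0.117), and in 8-cell embryos neither passed (0.336 and 0.988). In blastocyst-derived cells the donor-high miRNAs were lower by -0.54 (6.82e-35) and the oocyte-high miRNAs higher by 0.58 (1.57e-28). The oocyte-high set changed direction without IVF blastocyst-derived cell replicate 2 (0.148) and with library weights (0.0452). The calls in 2-cell embryos, morulae and blastocysts did not hold with the estimated correlation. In blastocyst-derived cells they held with sets of 50 (0.00228 and 0.0131) and with sets of up to 100 (0.00269 with 57 members and 0.0268 with 98), but not with sets of 25 (0.119 and 0.0943) or among miRNAs only (0.337 for each). Across the 582 tested miRNAs, which are not independent replicates, the NT minus IVF change correlated with the fibroblast minus oocyte change at r = 0.032 (Spearman 0.042) in 2-cell embryos, -0.111 (-0.142) in 8-cell embryos, -0.449 (-0.423) in morulae, where the 2 IVF libraries that stand apart are included, 0.237 (0.204) in blastocysts and -0.401 (-0.381) in blastocyst-derived cells. IVF embryos had a Holstein sire and NT embryos a cross-bred donor, so production method was not the only difference between them. The NT donor was a bull, so the sex of the embryos may differ between NT and IVF too, and it was not tested. The camera p-values here compare each set with the other sncRNAs or miRNAs tested, at the stated correlation. They do not measure the spread between pools. The limma and permutation p-values above rest only on the spread between pools and cultures.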

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

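The tests of the IVF morula library and of the 2-cell calls, and the single-library and scaling tests of the DLK1-DIO3 list, were chosen after the result was seen. The test with an epithelial covariate was written before, and its values over libraries and with the estimated correlation were added after.

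Groups of 4 libraries were searched for a lone library by Dixon's test on 16 measures. Of 96 groups, 6 held one, and chance finds about 5% of groups, or 4.8. In IVF morulae, replicate 1 had a miRNA share of 63.9% against 3.21% to 4.61% in the others. In NT 2-cell embryos, replicate 3 had a piRNA share of 82.1% against 90.3% to 91.7%, and a tRNA-derived share of 10.3% against 3.84% to 4.31%. NT 2-cell replicate 4 held all 12345 sequences of the table against 5513 to 6606, had 1639799 listed reads against 390689 to 579327, and a mean of the miR-17-92 list of 6.24 against 5.58 to 5.67 on the log2 scale.

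The NT steps were set against the IVF steps by interaction tests. From 2-cell to 8-cell limma called 7 sncRNAs, but the fit of only these groups called 0 (265 at an unadjusted p under 0.05), and 43 of 60 splits of the libraries called as many. From morula to blastocyst the blood and serum list was lower in the NT step (camera adjusted p = 0.0254, estimated 0.993). From blastocyst to derived cells the DLK1-DIO3 list was lower in the NT step (4.78e-29, estimated 2.4e-05), and the miR-17-92 (0.00112, estimated 0.563), epithelial (1.12e-08, estimated 0.108) and miR-34 and miR-449a-d (0.000431, estimated 0.234) lists were higher. Of these lists, DLK1-DIO3 alone held with the estimated correlation.

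IVF morula replicate 1 resembled blastocyst-derived cells. Its mean correlation with the 7 blastocyst-derived cell libraries was 0.944, above the lowest value of 0.869 between those libraries themselves, so a wrong label or tube may be the cause. Morulae mixed with cultured cells, with at least 5% of the RNA from morulae, are argued against, since its piRNA share allows at most 0.348% of RNA from morulae against the lowest of 5 other morula libraries, and 1.11% if IVF morula replicate 3, low in reads and piRNAs, is counted too. Variation in stage between pools is argued against by a piRNA share of 0.164%, far below the lowest blastocyst library at 14.3%. The label itself could not be checked.

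The called sncRNAs between NT and IVF 2-cell embryos were nearly all higher in NT. Whether the choice of sequences, all of them held by replicate 4, is the cause of the skew cannot be told apart: without that library 71.0% of calls were higher in NT (176 higher, 72 lower), but the list stays chosen by it. A spread shared with stages at which most sequences lie at the lowest value may explain the calls: the simulated comparison gave 612 false calls, and the fit of only the 2-cell libraries called 0 in the data (269 at an unadjusted p under 0.05 by limma). Scaling cannot be told apart. With libraries centred on their medians 0 were called, but this does not isolate scaling. Of 12345 sequences, the 2-cell libraries other than NT replicate 4 held 5513 to 6606. Where most tested sequences are not held the median is the lowest value, so centring follows detection as well. These calls are best read as unsettled, and genotype, the sex of the embryos and production method stay open.

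The DLK1-DIO3 list was lower in NT than in IVF blastocyst-derived cells. A single library is argued against: the second highest IVF library lies 1.16 above the highest NT library on the log2 scale, where the NT libraries span 0.13. The mean change was weakest without IVF blastocyst-derived cell replicate 3, at -0.79 ± 0.34 (SE), and the highest adjusted p with the estimated correlation and any library left out was 1.94e-06. Scaling and depth are argued against as the cause of the median gap. Before any scaling the median reads of the list in NT were 2.60% of those in IVF (4 to 18 reads against 25 to 750). The NT libraries held more listed reads at the median. They are not argued against for the full separation of the libraries. The highest NT library passed the lowest IVF library in CPM of miRNA reads (12.4 against 10.1) and with quantile normalisation (list mean 2.63 against 2.47). A different share of epithelial cells cannot be told apart: the bound set in advance was met with a covariate (adjusted p = 2.87e-06 with the preset correlation, mean change from -1.42 to -1.26), but over 7 libraries that change has an SE of 0.48 (p = 0.0568 by linear model), and the adjusted p is 0.53 with the estimated correlation. Production method, the bulls, the sex of the embryos and the cultures stay open and were not tested. A test of the library means alone gave an exact permutation p of 0.0571 (adjusted p = 0.794 over 50 tests). It cannot decide, since a lone smallest possible p of 0.0286 would not pass over 50 tests.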

How the results depend on the processing

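The tests without the IVF morula libraries labelled replicates 1 and 3, on log2 CPM, with voom, among miRNAs only, with mismatched forms and on shares of recovered reads were chosen after the data were seen. The alternatives below changed a count by over 1.5 times, a call or a direction, and the cause was not tested. With the 14 alternatives run on it, at the preset correlation, the DLK1-DIO3 list in NT against IVF blastocyst-derived cells kept its direction and call. Its camera adjusted p lay between 3.4e-119 and 1.74e-08. In the fit of only these cells the call was lost with the estimated correlation (camera adjusted p = 0.54). Median centring left its mean change at -0.92, so it adds no separate test. The let-7 and fibroblast lists from blastocyst to derived cells also kept theirs in all 14. All other list p-values in this part use the preset correlation too. Of the class share differences, 244 of their alternative values had the same direction and 26 did not. Of the values of named sncRNAs, 2976 kept direction and call, 790 lost the call and 10 changed direction.

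No filter on low values moved the number of called sncRNAs to 2 in NT vs IVF, 8-cell (1 higher, 1 lower). Lists that changed direction were oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.946).

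The stricter filter moved the number of called sncRNAs to 11 in NT vs IVF, 2-cell (11 higher, 0 lower), 0 in NT vs IVF, 8-cell, 49 in IVF, oocyte to 2-cell (32 higher, 17 lower) and 4 in IVF, morula to blastocyst (3 higher, 1 lower). It was 32 in NT, oocyte to 2-cell (30 higher, 2 lower), 0 in NT, 2-cell to 8-cell, 1398 in NT, morula to blastocyst (11 higher, 1387 lower) and 1 in NT step minus IVF step, 2-cell to 8-cell (0 higher, 1 lower). Lists that lost the call were donor-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.117), oocyte-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.0723) and oocyte-high miRNAs in NT vs IVF, morula (adjusted p = 0.179). Lists that gained a call were donor-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.0174) and donor-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.0165).

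Median centring moved the number of called sncRNAs to 0 in NT vs IVF, 2-cell, 0 in NT vs IVF, 8-cell, 0 in NT vs IVF, blastocyst and 0 in IVF, 2-cell to 8-cell. It was 4 in IVF, 8-cell to morula (4 higher, 0 lower), 0 in IVF, morula to blastocyst, 400 in IVF, blastocyst to derived cells (73 higher, 327 lower) and 200 in NT, 2-cell to 8-cell (0 higher, 200 lower). It was 198 in NT, 8-cell to morula (196 higher, 2 lower), 3 in NT, morula to blastocyst (3 higher, 0 lower), 1 in NT step minus IVF step, 2-cell to 8-cell (0 higher, 1 lower) and 2371 in fibroblasts vs oocytes (471 higher, 1900 lower). The call was lost for donor-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.128) and oocyte-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.09). A change of direction was seen for donor-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.462) and oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.0771).

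Quantile normalisation moved the number of called sncRNAs to 38 in NT vs IVF, 2-cell (23 higher, 15 lower), 12 in NT vs IVF, 8-cell (1 higher, 11 lower), 18 in NT vs IVF, blastocyst (5 higher, 13 lower) and 6 in NT vs IVF, blastocyst-derived cells (2 higher, 4 lower). It was 188 in IVF, oocyte to 2-cell (53 higher, 135 lower), 28 in IVF, 2-cell to 8-cell (18 higher, 10 lower), 865 in IVF, 8-cell to morula (80 higher, 785 lower) and 105 in IVF, morula to blastocyst (101 higher, 4 lower). It was 1622 in IVF, blastocyst to derived cells (402 higher, 1220 lower), 155 in NT, oocyte to 2-cell (55 higher, 100 lower), 17 in NT, 2-cell to 8-cell (2 higher, 15 lower) and 358 in NT, 8-cell to morula (126 higher, 232 lower). It was 417 in NT, morula to blastocyst (148 higher, 269 lower), 1238 in NT, blastocyst to derived cells, 15 in NT step minus IVF step, 2-cell to 8-cell (4 higher, 11 lower) and 1 in NT step minus IVF step, 8-cell to morula (0 higher, 1 lower). It was 28 in NT step minus IVF step, morula to blastocyst (1 higher, 27 lower) and 4 in NT step minus IVF step, blastocyst to derived cells (0 higher, 4 lower). No longer called were donor-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.15), oocyte-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.15) and oocyte-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.124). Lists that gained a call were donor-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.00397). It changed the direction of miR-660 in fibroblasts vs oocytes (0.16), miR-122 in fibroblasts vs oocytes (0.58), let-7f-1-5p/let-7f-2-5p in fibroblasts vs oocytes (0.51), miR-20a-5p in fibroblasts vs oocytes (0.04), miR-34b-3p in fibroblasts vs oocytes (0.55), miR-9-5p in fibroblasts vs oocytes (0.64), miR-9-2-5p/miR-9-1-5p in fibroblasts vs oocytes (1.96), miR-9-2-3p/miR-9-1-3p in fibroblasts vs oocytes (1.99) and miR-34c in fibroblasts vs oocytes (0.02).

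Removing the offset of the transformation moved the number of called sncRNAs to 2 in NT vs IVF, 8-cell (1 higher, 1 lower), 2 in IVF, 2-cell to 8-cell (2 higher, 0 lower), 0 in IVF, morula to blastocyst and 508 in NT, morula to blastocyst (10 higher, 498 lower). It was 569 in NT, blastocyst to derived cells.

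Fitting only the groups compared moved the number of called sncRNAs to 0 in NT vs IVF, 2-cell, 9 in NT vs IVF, 8-cell (3 higher, 6 lower), 2 in NT vs IVF, blastocyst (0 higher, 2 lower) and 11 in IVF, oocyte to 2-cell (10 higher, 1 lower). It was 411 in IVF, 8-cell to morula (0 higher, 411 lower), 0 in IVF, morula to blastocyst, 1443 in IVF, blastocyst to derived cells (203 higher, 1240 lower) and 31 in NT, oocyte to 2-cell (20 higher, 11 lower). It was 4 in NT, 2-cell to 8-cell (2 higher, 2 lower), 1345 in NT, 8-cell to morula (75 higher, 1270 lower), 2636 in NT, morula to blastocyst (97 higher, 2539 lower) and 1617 in NT, blastocyst to derived cells (314 higher, 1303 lower). It was 0 in NT step minus IVF step, 2-cell to 8-cell, 1 in NT step minus IVF step, 8-cell to morula (1 higher, 0 lower), 1 in NT step minus IVF step, morula to blastocyst (0 higher, 1 lower) and 2 in NT step minus IVF step, blastocyst to derived cells (2 higher, 0 lower). Lists that lost the call were donor-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.059), oocyte-high miRNAs in NT vs IVF, morula (adjusted p = 0.761) and tRNA fragments, Leu in NT vs IVF, blastocyst-derived cells (adjusted p = 0.092). Lists that gained a call were donor-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.00588). The direction changed for oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.588).

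eBayes without a trend moved the number of called sncRNAs to 8 in NT vs IVF, 8-cell (6 higher, 2 lower), 0 in NT vs IVF, blastocyst, 33 in IVF, 2-cell to 8-cell (9 higher, 24 lower) and 3 in IVF, morula to blastocyst (3 higher, 0 lower). It was 620 in NT, morula to blastocyst (12 higher, 608 lower) and 11 in NT step minus IVF step, 2-cell to 8-cell (1 higher, 10 lower). Lists that changed direction were oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.857).

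Library weights moved the number of called sncRNAs to 33 in NT vs IVF, 2-cell (33 higher, 0 lower), 39 in NT vs IVF, 8-cell (29 higher, 10 lower), 336 in NT vs IVF, blastocyst (19 higher, 317 lower) and 112 in NT vs IVF, blastocyst-derived cells (29 higher, 83 lower). It was 109 in IVF, oocyte to 2-cell (23 higher, 86 lower), 30 in IVF, 2-cell to 8-cell (11 higher, 19 lower), 374 in IVF, 8-cell to morula (2 higher, 372 lower) and 0 in IVF, morula to blastocyst. It was 2568 in IVF, blastocyst to derived cells (304 higher, 2264 lower), 69 in NT, oocyte to 2-cell (43 higher, 26 lower), 27 in NT, 2-cell to 8-cell (3 higher, 24 lower) and 1240 in NT, 8-cell to morula (17 higher, 1223 lower). It was 3156 in NT, morula to blastocyst (13 higher, 3143 lower), 2214 in NT, blastocyst to derived cells (297 higher, 1917 lower), 16 in NT step minus IVF step, 2-cell to 8-cell (0 higher, 16 lower) and 7 in NT step minus IVF step, 8-cell to morula (3 higher, 4 lower). It was 217 in NT step minus IVF step, blastocyst to derived cells (195 higher, 22 lower). The call was lost for oocyte-high miRNAs in NT vs IVF, morula (adjusted p = 0.137). Lists that gained a call were donor-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.042). A change of direction was seen for epithelial and trophectoderm in NT vs IVF, blastocyst-derived cells (adjusted p = 0.00482), miR-34 and miR-449a-d family in NT vs IVF, blastocyst-derived cells (adjusted p = 0.114) and oocyte-high miRNAs in NT vs IVF, blastocyst-derived cells (adjusted p = 0.0452).

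The replicate number as a block moved the number of called sncRNAs to 0 in NT vs IVF, 8-cell, 1 in IVF, 2-cell to 8-cell (1 higher, 0 lower), 0 in IVF, morula to blastocyst and 23 in NT, morula to blastocyst (5 higher, 18 lower). The direction changed for oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.934). The block changed the call of no other count or list, and 12 of 202 named sncRNAs lost their call with it. The replicate numbers were not treated as pairs, since the correlation of NT with IVF libraries of the same number and stage, after removal of group means, ran from -0.087 to 0.466. Some of these pairs were alike, so a shared origin of some is not excluded. Across all groups, libraries of the same number had a mean correlation of 0.015 over 204 pairs, against -0.005 over 603 pairs of different numbers, and 18 of 42 libraries correlated best with their own number.

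Adjustment within each class moved the number of called sncRNAs to 2 in NT vs IVF, 8-cell (1 higher, 1 lower), 2 in NT vs IVF, morula (2 higher, 0 lower), 25 in IVF, morula to blastocyst (24 higher, 1 lower) and 251 in NT, morula to blastocyst (9 higher, 242 lower). It was 1 in NT step minus IVF step, 8-cell to morula (1 higher, 0 lower).

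Taking the mean of the deposited values of a class in place of its share changed the direction of NT minus IVF for miRNA share, 2-cell (0.0308), miRNA share, 8-cell (0.144), miRNA share, morula (0.33), miRNA share, blastocyst (-0.147), miRNA share, all stages (0.0806), tRNA-derived share, 2-cell (0.289), tRNA-derived share, 8-cell (0.211), tRNA-derived share, morula (0.494) and tRNA-derived share, all stages (0.166).

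Sets of 25 and 25 miRNAs: lists that lost the call were donor-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.135) and oocyte-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.0965).

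Sets of 100 and 100 miRNAs: lists that changed direction were oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.82).

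Leaving out the IVF morula libraries labelled replicates 1 and 3 moved the number of called sncRNAs to 4 in NT vs IVF, 8-cell (3 higher, 1 lower), 4 in NT vs IVF, morula (0 higher, 4 lower), 52 in IVF, 2-cell to 8-cell (20 higher, 32 lower) and 11 in IVF, 8-cell to morula (8 higher, 3 lower). It was 1687 in IVF, morula to blastocyst (30 higher, 1657 lower), 1086 in IVF, blastocyst to derived cells (157 higher, 929 lower), 1614 in NT, 8-cell to morula (62 higher, 1552 lower) and 1671 in NT, morula to blastocyst (23 higher, 1648 lower). It was 801 in NT, blastocyst to derived cells (172 higher, 629 lower) and 8 in NT step minus IVF step, 8-cell to morula (0 higher, 8 lower). Lists that changed direction were oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.546), donor-high miRNAs in NT vs IVF, morula (adjusted p = 7.61e-05) and oocyte-high miRNAs in NT vs IVF, morula (adjusted p = 0.148). It changed the direction of NT minus IVF for miRNA share, morula (1.06), miRNA share, all stages (1.68), piRNA share, morula (-14.3), piRNA share, all stages (-1.29) and tRNA-derived share, morula (10.7). It changed the direction of miR-205-5p in IVF, 8-cell to morula (0.03).

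log2 CPM of listed reads moved the number of called sncRNAs to 0 in NT vs IVF, 2-cell, 0 in NT vs IVF, 8-cell, 11 in NT vs IVF, morula (11 higher, 0 lower) and 8 in NT vs IVF, blastocyst-derived cells (1 higher, 7 lower). It was 1 in IVF, oocyte to 2-cell (1 higher, 0 lower), 3 in IVF, 2-cell to 8-cell (3 higher, 0 lower), 159 in IVF, 8-cell to morula (88 higher, 71 lower) and 2 in IVF, morula to blastocyst (2 higher, 0 lower). It was 7521 in IVF, blastocyst to derived cells (180 higher, 7341 lower), 0 in NT, oocyte to 2-cell, 2 in NT, 2-cell to 8-cell (0 higher, 2 lower) and 107 in NT, 8-cell to morula (60 higher, 47 lower). It was 83 in NT, morula to blastocyst (38 higher, 45 lower), 3809 in NT, blastocyst to derived cells (164 higher, 3645 lower), 1 in NT step minus IVF step, 2-cell to 8-cell (0 higher, 1 lower) and 1 in NT step minus IVF step, 8-cell to morula (1 higher, 0 lower). It was 1 in NT step minus IVF step, morula to blastocyst (0 higher, 1 lower) and 2 in NT step minus IVF step, blastocyst to derived cells (1 higher, 1 lower). No longer called were oocyte-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.118). Lists that gained a call were donor-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.000146).

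Voom on recovered reads moved the number of called sncRNAs to 0 in NT vs IVF, 2-cell, 0 in NT vs IVF, 8-cell, 18 in NT vs IVF, morula (18 higher, 0 lower) and 0 in IVF, oocyte to 2-cell. It was 0 in IVF, 2-cell to 8-cell, 193 in IVF, 8-cell to morula (18 higher, 175 lower), 4 in IVF, morula to blastocyst (0 higher, 4 lower) and 11053 in IVF, blastocyst to derived cells (184 higher, 10869 lower). It was 0 in NT, oocyte to 2-cell, 2 in NT, 2-cell to 8-cell (0 higher, 2 lower), 2362 in NT, morula to blastocyst (18 higher, 2344 lower) and 1858 in NT, blastocyst to derived cells (158 higher, 1700 lower). It was 1 in NT step minus IVF step, 2-cell to 8-cell (0 higher, 1 lower), 1 in NT step minus IVF step, 8-cell to morula (1 higher, 0 lower), 1 in NT step minus IVF step, morula to blastocyst (0 higher, 1 lower) and 1 in NT step minus IVF step, blastocyst to derived cells (1 higher, 0 lower). It was 11380 in fibroblasts vs oocytes (112 higher, 11268 lower). Lists that lost the call were donor-high miRNAs in NT vs IVF, morula (adjusted p = 0.481) and oocyte-high miRNAs in NT vs IVF, blastocyst (adjusted p = 0.626). Lists that gained a call were donor-high miRNAs in NT vs IVF, blastocyst (adjusted p = 2.34e-06).

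Testing only miRNAs: lists that lost the call were donor-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.514) and oocyte-high miRNAs in NT vs IVF, 2-cell (adjusted p = 0.514). A change of direction was seen for donor-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.946) and oocyte-high miRNAs in NT vs IVF, 8-cell (adjusted p = 0.145).

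With each library left out in turn, the number of called sncRNAs ranged from 273 (without Oo replicate 1) to 697 (without NT 2c replicate 3) for NT, oocyte to 2-cell, from 236 (without IVF 2c replicate 3) to 877 (without NT 2c replicate 3) for NT vs IVF, 2-cell and from 0 (without IVF 2c replicate 2) to 196 (without IVF 2c replicate 3) for IVF, 2-cell to 8-cell. It ranged from 7 (without NT 8c replicate 4) to 48 (without NT 2c replicate 3) for NT step minus IVF step, 2-cell to 8-cell, from 0 (without IVF 8c replicate 2) to 11 (without NT 8c replicate 2) for NT vs IVF, 8-cell and from 0 (without IVF 8c replicate 2) to 2649 (without IVF Mo replicate 4) for IVF, 8-cell to morula. It ranged from 0 (without IVF 8c replicate 2) to 1 (without IVF Mo replicate 1) for NT step minus IVF step, 8-cell to morula, from 0 (without IVF Mo replicate 1) to 664 (without IVF Mo replicate 4) for NT vs IVF, morula and from 0 (without IVF Mo replicate 3) to 25 (without IVF Mo replicate 1) for IVF, morula to blastocyst. It ranged from 0 (without IVF Mo replicate 1) to 353 (without IVF Mo replicate 2) for NT step minus IVF step, morula to blastocyst, from 0 (without IVF Bl replicate 4) to 1 (without IVF Bl replicate 2) for NT vs IVF, blastocyst and from 330 (without IVF Bl replicate 3) to 513 (without IVF BDC replicate 2) for IVF, blastocyst to derived cells. It ranged from 45 (without NT 8c replicate 4) to 232 (without NT 2c replicate 3) for NT, 2-cell to 8-cell, from 153 (without NT 8c replicate 3) to 1470 (without NT 8c replicate 2) for NT, 8-cell to morula and from 0 (without NT Mo replicate 2) to 165 (without NT Bl replicate 2) for NT, morula to blastocyst. It ranged from 181 (without NT BDC replicate 4) to 311 (without NT Bl replicate 4) for NT, blastocyst to derived cells.

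With each library left out in turn, the adjusted p of lists ranged from 1.73e-05 (without IVF 2c replicate 1) to 0.708 (without IVF 2c replicate 3) for donor-high miRNAs in NT vs IVF, 2-cell, from 0.000504 (without NT 2c replicate 1) to 0.298 (without NT 2c replicate 4) for oocyte-high miRNAs in NT vs IVF, 2-cell and from 0.00814 (without NT 8c replicate 4) to 0.879 (without IVF 8c replicate 4) for donor-high miRNAs in NT vs IVF, 8-cell. It ranged from 0.446 (without IVF 8c replicate 2) to 0.998 (without NT 8c replicate 2) for oocyte-high miRNAs in NT vs IVF, 8-cell, from 3.36e-11 (without IVF Mo replicate 2) to 0.00526 (without IVF Mo replicate 1) for donor-high miRNAs in NT vs IVF, morula and from 1.17e-08 (without IVF Mo replicate 2) to 0.802 (without IVF Mo replicate 3) for oocyte-high miRNAs in NT vs IVF, morula. It ranged from 0.000151 (without NT Bl replicate 2) to 0.924 (without IVF Bl replicate 3) for donor-high miRNAs in NT vs IVF, blastocyst, from 5.49e-48 (without IVF BDC replicate 3) to 0.000676 (without IVF BDC replicate 2) for epithelial and trophectoderm in NT vs IVF, blastocyst-derived cells and from 2.12e-32 (without IVF BDC replicate 3) to 0.569 (without IVF BDC replicate 2) for miR-34 and miR-449a-d family in NT vs IVF, blastocyst-derived cells. It ranged from 1e-57 (without IVF BDC replicate 3) to 0.148 (without IVF BDC replicate 2) for oocyte-high miRNAs in NT vs IVF, blastocyst-derived cells.

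With each library left out in turn, NT minus IVF ranged from -2.51 (without IVF BDC replicate 1) to 1.76 (without IVF Mo replicate 1) for miRNA share, all stages, from -0.162 (without IVF 2c replicate 3) to 6.01 (without NT 2c replicate 3) for piRNA share, 2-cell and from -3 (without NT 2c replicate 3) to 0.454 (without IVF 2c replicate 3) for tRNA-derived share, 2-cell. It ranged from -0.783 (without NT 8c replicate 4) to 0.481 (without IVF 8c replicate 4) for miRNA share, 8-cell, from -18.8 (without IVF Mo replicate 3) to 1.46 (without IVF Mo replicate 1) for miRNA share, morula and from -13.4 (without NT Mo replicate 3) to 6.41 (without IVF Mo replicate 3) for tRNA-derived share, morula. It ranged from -8.05 (without IVF Bl replicate 2) to 4.07 (without IVF Bl replicate 4) for tRNA-derived share, blastocyst, from -0.045 (without IVF BDC replicate 1) to 12.1 (without IVF BDC replicate 4) for miRNA share, blastocyst-derived cells and from -10.7 (without IVF BDC replicate 3) to 0.0591 (without IVF BDC replicate 1) for tRNA-derived share, blastocyst-derived cells.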

Other observations

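The splits of the libraries were set before the data were examined, and the simulations and the other values in this part were chosen after the data were seen. Each count of called sncRNAs was set beside the counts from other splits of the same libraries into groups of the same sizes, the real split included.

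In 3 comparisons with many calls, 1 of 35 splits called as many, the smallest share 35 splits can give. They were IVF blastocyst to derived cells (622, highest other 117), NT morula to blastocyst (166, highest other 0) and NT blastocyst to derived cells (345, highest other 46). Their real counts lay above those of all other splits. This share is not corrected over the comparisons and cannot fall lower, so it does not exclude chance. The NT morula to blastocyst count was 0 without NT morula replicate 2 and 3 higher and 0 lower with median centring, so it is not stable even so. In NT against IVF blastocysts 1 of 35 splits called as many too, but 1 call against a highest other of 0 is too little to exclude chance, and that call is lost without IVF blastocyst replicate 4. Chance cannot be excluded in NT against IVF 2-cell embryos (275 called, 15 of 35 splits, highest other 834) and 8-cell embryos (1, 20 of 35, highest other 57). A real count of 0 is reached by every split, so the splits test nothing in morulae (highest other 1943) and blastocyst-derived cells (highest other 1). The unadjusted counts by limma for the last 2 were 1223 and 33.

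Among IVF steps chance cannot be excluded for oocyte to 2-cell (365 called, 6 of 35 splits, highest other 471), 2-cell to 8-cell (14, 13 of 35, highest other 385), 8-cell to morula (1535, 5 of 35, highest other 2604) and morula to blastocyst (1, 18 of 35, highest other 1576). Among NT steps it cannot be excluded for oocyte to 2-cell (293, 22 of 35, highest other 736), 2-cell to 8-cell (60, 25 of 35, highest other 854) and 8-cell to morula (765, 2 of 35, highest other 1037). Why some splits call several times the real count was not tested.

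For the difference between NT and IVF steps, chance cannot be excluded for 2-cell to 8-cell (7 called, 43 of 60 splits, highest other 730). The splits test nothing where the real count was 0. This holds for 8-cell to morula (highest other 1576), morula to blastocyst (highest other 1028) and blastocyst to derived cells (highest other 0). By limma 577, 846 and 37 sncRNAs of the last 3 had an unadjusted p under 0.05, and fits of only these groups called 1, 1 and 2. Fibroblasts against oocytes make only 10 splits, too few for a share under 0.05 (5029 called, 1 split as large, highest other 4).

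Libraries within a group differed in how alike they were. Correlations lay between 0.97 and 0.979 in NT blastocyst-derived cells and between 0.276 and 0.792 in IVF morulae. Library weights called 336 sncRNAs between NT and IVF blastocysts against 1 with equal weights, and 33 against 275 in 2-cell embryos. In the simulations, 8-fold changes were found in 25.8% of cases in blastocysts with the shared spread and in 100% with the blastocyst libraries alone. A single spread for all stages may therefore hide changes in late stages and add calls in early ones, as the 612 false calls in simulated 2-cell embryos show for the latter.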
